A study of Arabidopsis thaliana with 15 samples.

How the data were processed

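Transcripts were measured in seedlings of Arabidopsis thaliana, 15 libraries in 5 groups of 3, at 11 days of age. Per the labels, seedlings were grown on plates of Murashige and Skoog medium at 22 °C under 16 h of light and 8 h of dark. Per the labels, total RNA was extracted with TRIzol and sequenced on a NovaSeq 6000 as 150-bp paired-end reads. The submitters' processing notes name bcl2fastq, HISAT2 and edgeR as the tools the authors used and TAIR10 as the genome build. The role of each tool, versions, settings, the strandedness of the libraries and the gene annotation were not given in the sources used here, so reads from overlapping or opposite genes could not be told apart. The deposited table holds 1 value per gene and library, in a unit recorded here as signal because no source states it. From the values themselves, which are never negative and not whole, they had the form of read counts moved by the authors to 1 common library size, with an adjustment within each group that edgeR makes for its pseudo-counts. Such an adjustment uses the groups, so the spread between replicates may differ from that of the raw counts. The value of 1 read had a geometric mean of 1.017 over the 15 libraries.

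The table used holds no raw counts, so the count-based test that had been planned, and the alternatives that need counts, were not run, and the test planned for other units was used. Values were taken as log2(value + 1), and genes with a mean of at least 1 in at least 1 group were kept, 25085 of 32548. Another 6167 genes were listed at 0 in every library. Values under 1e-06 were treated as 0. A limma-trend model (limma 3.58.1 in R 4.3.3) was fitted to all 15 libraries with 5 groups. Gene names were joined by locus to the reference annotation of assembly TAIR10.1, and all 32548 loci matched. That assembly differs from the TAIR10 of the deposited table, so no coordinates were used.

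Each mutant was compared with both wild-type sets, because the labels do not tie a set to a mutant. A gene was changed where it differed in the same direction from both sets. The larger p-value of both was kept and adjusted over the genes tested by the Benjamini-Hochberg method, with a threshold of 0.05, and fold changes were taken against the mean of both sets. The mutants labelled wrky-qm_15_hz and obe1-2 were also compared with wrky-qm, and the wild-type sets with each other. The comparison of obe1-2 with wrky-qm_15_hz was added after the data were seen. Overlaps of changed genes were set beside the product of the list sizes over the genes tested, beside simulated unchanged groups that share the controls, and beside fits with the controls split. The way zeros are stored pairs Col-0_1 with wrky-qm and Col-0_2 with the other mutants, so numbers of changed genes and called lists against those sets alone are printed beside the pooled ones, while fold changes and list medians are given against the mean of both sets.

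Gene lists were fixed before the values were seen: 22 lists with 276 members, of which 270 matched the reference names and 6 (OBE3, OBE4, SARD4, GRXC9, UPOX and HSP70-4) were left out, and 4 families taken by symbol. The lists were group IId WRKY genes, OBERON genes, salicylic acid, pattern-triggered immunity, jasmonate, camalexin and indole glucosinolates, abscisic acid and drought, cold, oxidative and mitochondrial stress, heat shock, unfolded protein response, photosynthesis, meristem and vascular patterning, auxin response, cell division, senescence, phosphate starvation, iron deficiency, circadian clock, root hair with endodermis and suberin, seed storage, and touch and handling. The families were WRKY, cysteine-rich receptor-like kinases, tau-class glutathione transferases (GSTU) and ethylene response factors (ERF). The 25 lists with at least 5 members were tested with camera in limma at a preset correlation of 0.01, once against each wild-type set. The larger p-value was kept, or 1 where the directions differed, and adjusted over the 25 lists. Membership was written from memory of gene function, not from a database. List medians include members listed at 0 in some group, at most 3 per group in any list other than seed storage, and no median is given for seed storage.

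Genes were named by a rule fixed before the values were seen. It takes the mutated genes, the group IId WRKY and OBERON genes, and the 6 largest rises and 6 largest falls per mutant in which each mutant library lay beyond all 6 wild-type libraries. It adds up to 4 changed members of smallest p in each list with at least 3 changed members, 4 rising and 4 falling genes shared by all mutants, and the 4 largest differences in each direction between mutants and between wild-type sets. Examples in the text were taken from the genes so named, and 1 of these genes is not reported here.

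Library totals of 44049333 to 49934976 normalised reads gave a median replicate coefficient of variation between 3.63% and 4.76% in genes of mean 1000 or more. The 10 highest genes held between 4.84% and 7.32% of a library. The procedure was tested on simulated data from the wild-type libraries, with 24173 genes. At a mean of 50 or more it found 76.1%, 83.6% and 76.8% of genes changed 2-fold in wrky-qm, wrky-qm_15_hz and obe1-2. For genes changed 1.5-fold the shares were 62.1%, 56% and 55.1%. Over genes of any mean it found 52.2%, 68.7% and 64.2% of those changed 2-fold and 53.7%, 41.8% and 40.3% of those changed 1.5-fold. False calls over genes of any mean were 0, 1 and 1. Only 200 genes were changed per simulated mutant, far fewer than were called in the data. In a separate simulation for wrky-qm with 24151 genes, camera called 1 raised list of 20 genes and 0 of 99 unchanged lists. Genes were drawn independently there, so this does not test calls in lists of genes that move together.

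Alternatives tried were a fit on the libraries of the comparison alone, no low-value filter, quantile normalisation, a pseudocount of 0.1, the replicate number as a block, a 2-fold minimum, each wild-type set alone, both sets as 1 mean, split controls, an estimated correlation between genes and leaving out each library in turn. A minimum mean of 50 was added after the data were seen. Libraries were also regrouped at random into 100 splits per test, or 10 where only 6 libraries were compared. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.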

Results

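RNA was sequenced from Arabidopsis thaliana seedlings grown for 11 days on plates of Murashige and Skoog medium. The 15 libraries fell into 5 groups of 3. Col-0_1 and Col-0_2 were 2 sets of wild-type seedlings of the Col-0 ecotype. The labels name wrky-qm as a quintuple mutant of WRKY7, WRKY11, WRKY17, WRKY21 and WRKY39, which belong to the group IId family of WRKY transcription factors. They name wrky-qm_15_hz as the same combination with WRKY15, another group IId gene, mutated on 1 chromosome copy, and obe1-2 as a double mutant of OBE1 and OBE2. OBE1 and OBE2 encode OBERON proteins with a PHD finger, a domain known to bind histone tails, and the series title states that WRKY proteins of this kind act in a complex with PHD proteins to repress stress genes. The deposited values had the form of normalised read counts and summed to between 44049333 and 49934976 per library. Means are given ± SD over the 3 libraries of a group, in normalised reads. Log2 fold changes are given ± SE against the mean of both wild-type sets, on the log2(value + 1) scale, which understates the change of low genes. A gene was called changed where limma found it different in the same direction from both wild-type sets. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

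The mutated genes were examined first. OBE1 transcripts in obe1-2 were nearly absent, at 11.1 ± 4.66 against 2194 ± 161 in Col-0_1 and 2546 ± 109 in Col-0_2, and OBE2 (AT5G48160) stood at 1811 ± 75.8 against 3813 ± 111 and 4279 ± 128. Both falls passed the test, with log2 fold changes of -7.68 ± 0.14 for OBE1 (AT3G07780) (limma adjusted p = 5.84e-20) and -1.16 ± 0.038 for OBE2 (limma adjusted p = 4.63e-15). In wrky-qm, WRKY17 (AT2G24570) fell by 2.34 on the log2 scale, WRKY21 (AT2G30590) had a log2 fold change of -0.62 ± 0.065 and WRKY39 (AT3G04670) one of -0.53 ± 0.055, while WRKY7 (AT4G24240) rose by 0.84 ± 0.049 and WRKY11 (AT4G31550) by 0.56 ± 0.054 (largest limma adjusted p of these 5 = 6.63e-05). The libraries labelled wrky-qm_15_hz showed falls of WRKY17 (log2 fold change -1.19 ± 0.083) and WRKY39 (-0.82 ± 0.055) and rises of WRKY7 (0.46 ± 0.049) and WRKY11 (1.71 ± 0.054). WRKY21 did not pass there (log2 fold change -0.11 ± 0.065, limma adjusted p = 0.304). WRKY15 (AT2G23320) was higher than wild type in every mutant, with log2 fold changes of 1.81 ± 0.058 in wrky-qm, 1.56 ± 0.058 in wrky-qm_15_hz and 2.01 ± 0.058 in obe1-2. A transcript that is made can still carry a mutation, and counts per gene do not show which part of it was read. The levels of WRKY7, WRKY11 and WRKY15 therefore do not check the labels of the WRKY mutants, and directions drawn from those groups are for the libraries as labelled.

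**Figure D1:**
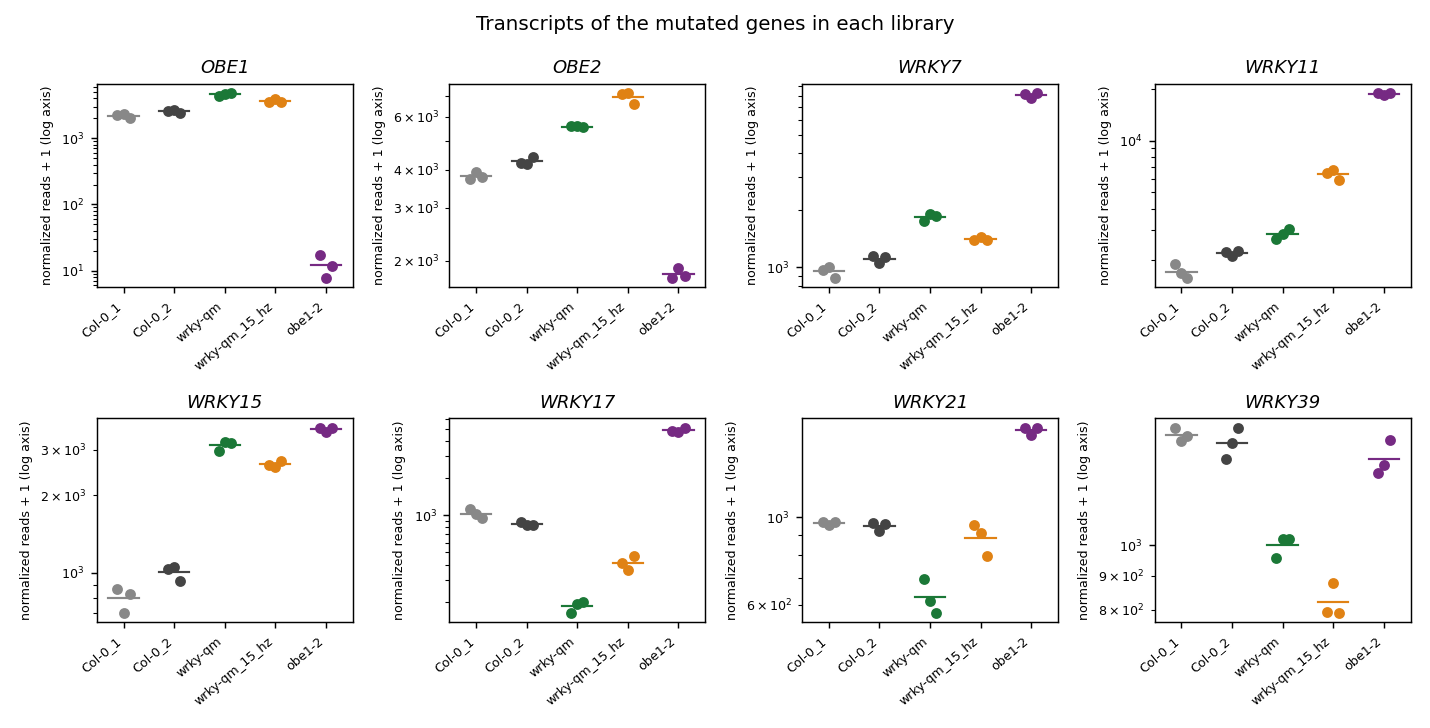
Normalised reads + 1 on a log axis for OBE1, OBE2 and 6 group IId WRKY genes. Each point is 1 library, each line a group mean, and the horizontal axis gives the 5 groups. OBE1 lay at 11.1 in obe1-2, and WRKY17 at 184 in wrky-qm against 1028 and 849 in the wild-type sets.

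In wrky-qm, transcripts of the abscisic acid and drought response rose as a group. Of 18 members tested, 17 rose and 1 fell, with a median log2 fold change of 2.32 (camera in limma, adjusted p = 9.84e-20). NCED3 (AT3G14440), which encodes the rate-limiting dioxygenase of abscisic acid synthesis, reached 13790 ± 236 against 1065 ± 90.2 and 902 ± 34.4 in the wild-type sets. The dehydration-responsive NAC factor RD26 (AT4G27410) rose by 3.58 ± 0.059, the phosphatase gene ABI1 (AT4G26080) by 1.93 ± 0.033 and ERD7 (AT2G17840) by 2.29 ± 0.038 on the log2 scale (largest limma adjusted p = 7.94e-19).

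Jasmonate synthesis and response genes rose too, 18 of 24 up and 3 down, with a median of 2.05 (camera adjusted p = 1.12e-10). OPR3 (AT2G06050), a reductase of jasmonate synthesis, rose by 2.33 ± 0.038, the lipoxygenase gene LOX3 (AT1G17420) by 3.26 ± 0.060 and the repressor genes JAZ9 (AT1G70700) and JAZ6 (AT1G72450) by 3.49 ± 0.054 and 2.17 ± 0.044. 3 defensin genes were among the largest falls. PDF1.3 (AT2G26010) stood at 0.652 ± 1.13 against 142 ± 32.02 in Col-0_1 and 1616 ± 136 in Col-0_2 (log2 fold change -8.37 ± 0.26), and PDF1.2 (AT5G44420) and PDF1.2c (AT5G44430) fell by 7.05 and 6.36 on the log2 scale. These defensins are close copies that could share reads, and the wild-type sets themselves differed in them. Among pattern-triggered immunity genes 16 of 21 rose and 0 fell, with a median of 1.66 (camera adjusted p = 2.67e-10). They included the receptor kinase gene SOBIR1 (AT2G31880) (1.84 ± 0.037), the transcription factor gene WRKY22 (AT4G01250) (3.25 ± 0.073) and the NADPH oxidase gene RBOHD (AT5G47910) (1.52 ± 0.038). Salicylic acid genes split, 9 up and 6 down of 23 (camera adjusted p = 1). CBP60G (AT5G26920) and SARD1 (AT1G73805), regulators of salicylic acid synthesis, rose by 2.41 ± 0.061 and 2.35 ± 0.14, while PR1 (AT2G14610), a marker of salicylic acid signalling, fell from 93.1 ± 16.3 and 59.9 ± 27.7 to 1.92 ± 3.31 (limma adjusted p = 2.07e-08).

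Iron deficiency genes rose in wrky-qm, 6 of 8 with 0 falling and a median of 2.44 (camera adjusted p = 1.23e-06). The paralogous transcription factor genes BHLH038 (AT3G56970), BHLH039 (AT3G56980), BHLH100 (AT2G41240) and BHLH101 (AT5G04150), which are induced in iron-starved plants, rose by 4.36 ± 0.15, 3.28 ± 0.13, 3.05 ± 0.11 and 2.95 ± 0.20. Cold response genes rose in 8 of 10 cases with 0 falling (median 1.27, camera adjusted p = 4.02e-05), among them ZAT10 (AT1G27730) (2.76 ± 0.084), CBF2 (AT4G25470) (2.43 ± 0.17) and COR15A (AT2G42540) (1.299 ± 0.058), which encodes a chloroplast cryoprotective protein. The touch list, used as a marker of handling, rose in 5 of 6 members (median 2.095, camera adjusted p = 0.00617), including the calmodulin-like genes TCH3 (AT2G41100) (3.04 ± 0.068) and TCH2 (AT5G37770) (1.72 ± 0.053). The same list differed between the wild-type sets by 1.897 in the median. Seed storage transcripts, markers of embryos or carried-over seed, rose in 6 of 9 members. The cruciferin gene CRC (AT4G28520) reached 4189 ± 90.6, was listed at 0 in Col-0_1 and stood at 44.5 ± 8.11 in Col-0_2, and the cruciferin gene CRA1 (AT5G44120) rose from 17.95 ± 4.95 and 358 ± 49.02 to 4783 ± 111. The seed storage call (camera adjusted p = 0.000759) was lost at adjusted p = 0.0814 with an estimated correlation. The WRKY family, 25 up and 6 down of 64, was called at adjusted p = 0.0266 with the preset correlation and lost at adjusted p = 0.171 with an estimated correlation, at 0.0511 with a minimum mean of 50 and at 0.0761 in a fit on its own libraries.

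The other 6 called lists held with an estimated correlation. Their camera adjusted p then ran from 0.000146 for abscisic acid and drought to 0.0429 for cold response and for touch. No call was made in wrky-qm for the lists that follow. Photosynthesis genes counted 3 up and 3 down of 24, cell division genes 0 up and 2 down of 12, meristem and vascular genes 0 up and 2 down of 16, and root genes 2 up and 5 down of 12. Camalexin and indole glucosinolate genes counted 4 up and 2 down of 11, oxidative stress genes 6 and 3 of 13, unfolded protein response genes 1 and 3 of 8, auxin response genes 3 and 1 of 10, senescence genes 5 and 1 of 7 and phosphate starvation genes 2 and 4 of 9. Heat shock genes counted 0 changed of 8 by limma. The group IId WRKY list held 3 up and 3 down of 7, and cysteine-rich receptor-like kinases (CRK) 15 up and 5 down of 39 (camera adjusted p = 0.073). The CRK family was called at adjusted p = 0.000537 against Col-0_1 alone, 0.00643 against the mean of both sets, 0.0315 after quantile normalisation and 0.0464 without Col-0_2 replicate 3. Senescence was called at adjusted p = 0.00682 against Col-0_1 alone and phosphate starvation at 0.0404 against Col-0_2 alone. Single members of these lists changed, such as the root-hair gene PRP3 (AT3G62680) (-1.32 ± 0.11), the nitrate transporter gene NRT2.1 (AT1G08090) (2.29 ± 0.053), the phosphate-responsive gene SPX1 (AT5G20150) (-1.25 ± 0.049), the senescence gene SAG13 (AT2G29350) (-3.35 ± 0.16) and CRK10 (AT4G23180) (2.85 ± 0.054). Adjusted over the list alone, the counts were 9 up for cold response, 8 up and 3 down for oxidative stress, 4 up and 4 down for photosynthesis and 18 up and 5 down for the CRK family, and otherwise as above. The largest rises over all genes, after CRC, were those of AT2G17680, which reached 355 ± 44.03 and was listed at 0 in Col-0_2, DDF1 (AT1G12610), a gene for a DREB-type factor that reached 549 ± 24.4 and was listed at 0 in Col-0_1, and AT1G24580, with a log2 fold change of 7.57 ± 0.25. Among the largest falls were the marneral synthase gene MRN1 (AT5G42600) (-6.32 ± 0.51) and PRB1 (AT2G14580), a basic form of PR1 (-6.02 ± 0.54).

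Of 25085 genes tested in wrky-qm, 6743 changed, 3886 up and 2857 down, and 2262 of these changed at least 2-fold, 1605 up and 657 down. Quantile normalisation gave 3292 up and 4480 down, so the excess of rises over falls turned with the scaling. Against Col-0_1 alone 10126 genes differed, 5507 higher and 4619 lower, and camera called 12 lists, and against Col-0_2 alone 10549. The way zeros are stored in the deposited table sets Col-0_1 and wrky-qm apart from the other 3 groups, although no label names a batch.

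In wrky-qm_15_hz, immune and defence transcripts rose and growth transcripts fell. All 21 pattern-triggered immunity genes rose, with a median log2 fold change of 2.51 (camera adjusted p = 5.17e-14). They included CYP81F2 (AT5G57220), a monooxygenase gene of indole glucosinolate modification (4.65 ± 0.066), WRKY29 (AT4G23550) (4.43 ± 0.093), SOBIR1 (2.24 ± 0.037) and RBOHD (1.96 ± 0.038). Salicylic acid genes rose in 18 of 23 cases and fell in 1 (median 1.35, camera adjusted p = 2.2e-06). CBP60G rose by 4.16 ± 0.061, SARD1 by 4.04 ± 0.14, PBS3 (AT5G13320), a salicylic acid synthesis gene, by 3.62 ± 0.094 and the glucosyltransferase gene UGT74F2 (AT2G43820) by 2.43 ± 0.040. Camalexin and indole glucosinolate genes counted 8 up and 2 down of 11 (median 1.801, camera adjusted p = 0.00115), with GSTF6 (AT1G02930) at 40496 ± 1612 against 1868 ± 69.1 and 2481 ± 51.2, and CYP71A12 (AT2G30750) up by 4.64 ± 0.10. The CRK family rose in 34 of 39 members and fell in 2 (median 2.01, camera adjusted p = 5.34e-11), with CRK22 (AT4G23300) up by 2.63 ± 0.041 and CRK18 (AT4G23260) by 3.11 ± 0.077.

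Jasmonate genes rose in 18 of 24 cases with 0 falling (median 1.41, camera adjusted p = 6.96e-07), among them LOX2 (AT3G45140) (1.59 ± 0.039), LOX4 (AT1G72520) (2.596 ± 0.11) and JAZ1 (AT1G19180) (2.31 ± 0.068). The WRKY family rose in 39 of 64 members and fell in 10 (median 1.77, camera adjusted p = 4.11e-06), with WRKY6 (AT1G62300) up by 2.32 ± 0.050 and WRKY22 by 3.75 ± 0.073. All 9 phosphate starvation genes rose (median 2.57, camera adjusted p = 6.96e-07), including the transporter genes PHT1;1 (AT5G43350) (2.57 ± 0.034) and PHT1;4 (AT2G38940) (3.02 ± 0.053), SPX1 (1.63 ± 0.049) and the noncoding RNA gene IPS1 (AT3G09922) (3.62 ± 0.14). PHT1;1 has a near-identical neighbour, so its reads are uncertain. Senescence genes counted 6 up and 1 down of 7 (median 2.39, camera adjusted p = 0.00058), with SAG13 up by 5.14 ± 0.16 and SAG21 (AT4G02380) by 3.02 ± 0.056. All 8 unfolded protein response genes rose (median 0.798, camera adjusted p = 0.0003), such as the disulfide isomerase gene PDI6 (AT1G77510) (0.96 ± 0.038) and the transcription factor gene BZIP60 (AT1G42990) (1.04 ± 0.044). Heat shock genes rose in 6 of 8 cases with 0 falling (median 2.25, camera adjusted p = 0.0163), including HSP90.1 (AT5G52640) (1.47 ± 0.075) and the heat shock factor gene HSFA2 (AT2G26150) (2.37 ± 0.25). The touch list rose in 5 of 6 members (median 2.17, camera adjusted p = 0.00588), with TCH4 (AT5G57560), a xyloglucan endotransglucosylase gene, up by 3.47 ± 0.061.

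Seed storage transcripts rose in 8 of 9 members (camera adjusted p = 3.5e-05) and led the rises of wrky-qm_15_hz over all genes. The 2S albumin genes SESA3 (AT4G27160) and SESA2 (AT4G27150) reached 4634 ± 81.3 and 4103 ± 326 and were listed at 0 in both wild-type sets. CRU2 (AT1G03880), a cruciferin gene, reached 3844 ± 193 and was listed at 0 in Col-0_1, and CRC reached 10916 ± 221. The albumin genes are close copies in a row, so reads could be shared among them. CYP82C2 (AT4G31970), a cytochrome P450 gene of indole carbonyl nitrile metabolism, rose to 2050 ± 39.6 and was listed at 0 in Col-0_1.

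Falling lists in wrky-qm_15_hz were those of growth and the chloroplast. Photosynthesis genes fell in 20 of 24 cases with 0 rising (median -0.64, camera adjusted p = 3.08e-07). LHCB2.1 (AT2G05100) and LHCB3 (AT5G54270), genes for light-harvesting proteins, had log2 fold changes of -1.403 ± 0.040 and -1.07 ± 0.043. All 12 cell division genes fell (median -1.34, camera adjusted p = 1.64e-05), including the mitotic cyclin gene CYCB1;2 (AT5G06150) (-1.67 ± 0.070) and the cytokinesis syntaxin gene KNOLLE (AT1G08560) (-1.66 ± 0.070). Meristem and vascular genes counted 1 up and 12 down of 16 (median -1.15, camera adjusted p = 0.00147), with TMO7 (AT1G74500) at -5.602 ± 0.30 and PLT2 (AT1G51190), a root stem cell factor, listed at 0 against 64.1 ± 7.79 and 43.9 ± 25.4. Root genes counted 1 up and 10 down of 12 (median -1.14, camera adjusted p = 0.00217), including the endodermal genes CASP1 (AT2G36100) (-1.97 ± 0.064) and CASP2 (AT3G11550) (-2.202 ± 0.13). NRT2.1 was the root gene that rose (2.32 ± 0.053).

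Lists without a call in wrky-qm_15_hz included abscisic acid and drought response, with 4 up and 10 down of 18 and a median of -0.695 (camera adjusted p = 0.0534). Its members RD29A (AT5G52310) (-2.83 ± 0.029), P5CS1 (AT2G39800), a proline synthesis gene (from 34509 ± 531 and 18663 ± 242 to 5919 ± 24.5), and NCED3 (-1.74 ± 0.059) fell. The list was called at adjusted p = 0.000541 against Col-0_2 alone, 0.0114 against the mean of both sets, 0.027 after quantile normalisation and 0.0471 without wrky-qm_15_hz replicate 3. Cold response genes counted 2 up and 6 down of 10 (camera adjusted p = 0.145) and were called at adjusted p = 0.00353 against Col-0_2 alone and 0.0244 against the mean of both sets, with COR15A at -2.67 ± 0.058 and CBF3 (AT4G25480) at -4.995 ± 0.24. Auxin response genes counted 2 up and 7 down of 10, iron deficiency genes 4 and 2 of 8, oxidative stress genes 8 and 3 of 13 and group IId WRKY genes 3 and 2 of 7. Auxin response was called at adjusted p = 0.0308 against Col-0_2 alone, and oxidative stress at 0.037 against Col-0_2 alone, 0.049 against the mean of both sets and 0.0496 after quantile normalisation. Adjusted over the list alone, the counts were 7 up for heat shock, 9 up for seed storage, 21 down for photosynthesis, 11 down for the WRKY family, 8 down for auxin response and 9 up for oxidative stress, and otherwise as above. The largest falls over all genes included MLP328 (AT2G01520), from 2241 ± 97.4 and 2243 ± 112 to 12.5 ± 2.84, and MYB76 (AT5G07700), a regulator of aliphatic glucosinolate synthesis (-6.93 ± 0.39).

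In wrky-qm_15_hz 13541 of 25085 genes changed, 6656 up and 6885 down, of which 6342 changed at least 2-fold, 2878 up and 3464 down. All 16 called lists held with an estimated correlation, at camera adjusted p up to 0.0381, the value for photosynthesis. Against Col-0_2 alone, the wild type with the same storage of zeros, 15344 genes differed, 7502 higher and 7842 lower, and camera called 20 lists. By the mean squared difference over the sum, replicate 3 stood farther from replicates 1 and 2 (17.1 and 11.996) than any other replicates of a group did, but not by correlation, and 12950 genes changed without it.

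In obe1-2, the defence lists that rose in wrky-qm_15_hz rose as well. Pattern-triggered immunity genes rose in 20 of 21 cases (median 2.702, camera adjusted p = 5.09e-11), with CYP81F2 up by 5.03 ± 0.066, WRKY29 by 4.93 ± 0.093 and WRKY22 by 4.17 ± 0.073. Salicylic acid genes rose in 19 of 23 cases with 0 falling (median 2.09, camera adjusted p = 4.03e-08). UGT74F2 rose by 3.26 ± 0.040, PBS3 by 3.998 ± 0.094 and UGT76B1 (AT3G11340), a glucosyltransferase gene of immune regulation, by 2.39 ± 0.057. PR1 stood at 28899 ± 842 against 93.1 ± 16.3 and 59.9 ± 27.7 (log2 fold change 8.63 ± 0.40). Camalexin and indole glucosinolate genes counted 8 up and 2 down of 11 (median 2.702, camera adjusted p = 0.000792), among them CYP83B1 (AT4G31500) (3.06 ± 0.029), CYP79B2 (AT4G39950) (2.64 ± 0.040) and GSTF6 (4.44 ± 0.047). The CRK family rose in 33 of 39 members and fell in 3 (median 2.61, camera adjusted p = 2.46e-10), with CRK22 up by 3.46 ± 0.041.

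WRKY family genes rose in 46 of 64 cases and fell in 6 in obe1-2 (median 2.21, camera adjusted p = 6.45e-09). The group IId list rose in 5 of 7 members with 0 falling, at log2 fold changes of 3.28 ± 0.054 for WRKY11, 2.97 ± 0.049 for WRKY7, 2.39 ± 0.083 for WRKY17 and 2.01 ± 0.058 for WRKY15. Its call (camera adjusted p = 0.00232) was lost at adjusted p = 0.0515 with an estimated correlation. WRKY39 did not pass (-0.102 ± 0.055, limma adjusted p = 0.296) but passed after quantile normalisation at limma adjusted p = 0.00453, as did WRKY74 (AT5G28650) at 0.00549. Jasmonate genes counted 18 up and 3 down of 24 (median 0.95, camera adjusted p = 0.000792). LOX2 rose by 2.51 ± 0.039 and LOX4 by 2.89 ± 0.11, while VSP2 (AT5G24770), a vegetative storage protein gene, fell from 9754 ± 878 and 4565 ± 127 to 252 ± 30.6. All 8 unfolded protein response genes rose (median 1.25, camera adjusted p = 0.000107), with PDI6 up by 1.37 ± 0.038 and the calnexin gene CNX1 (AT5G61790) by 0.74 ± 0.028. Senescence genes rose in 6 of 7 cases with 0 falling (median 2.98, camera adjusted p = 0.000792), including WRKY6 (2.98 ± 0.050) and the NAC factor gene NAC092 (AT5G39610) (3.102 ± 0.083).

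Growth and chloroplast lists fell in obe1-2. Photosynthesis genes fell in 23 of 24 cases with 0 rising (median -1.57, camera adjusted p = 5.64e-11), with LHCB3 at 45226 ± 2133 against 245490 ± 3538 and 244970 ± 8430 (log2 fold change -2.44 ± 0.043). All 12 cell division genes fell (median -2.45, camera adjusted p = 5.2e-06), with KNOLLE at -3.27 ± 0.070 and the kinase gene CDKB2;1 (AT1G76540) at -2.49 ± 0.095. Meristem and vascular genes counted 2 up and 12 down of 16 (median -1.97), with MP (AT1G19850), an auxin response factor of embryo patterning, at -1.76 ± 0.068 and PLT3 (AT5G10510) at -4.21 ± 0.17, and with TMO7 listed at 0. That call (camera adjusted p = 0.00179) was lost at adjusted p = 0.0515 with an estimated correlation. Cold response genes counted 2 up and 8 down of 10 (median -2.79, camera adjusted p = 0.0291), a call lost at adjusted p = 0.181 with an estimated correlation. COR15A fell from 14074 ± 869 and 12205 ± 903 to 221 ± 15.5, and KIN1 (AT5G15960) from 883 ± 222 and 1065 ± 155 to 10.8 ± 3.81.

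No call was made in obe1-2 for abscisic acid and drought response, with 5 up and 10 down of 18 and a median of -1.28 (camera adjusted p = 0.1). RD29A (-3.31 ± 0.029), P5CS1 (-3.37 ± 0.030) and NCED3 (-3.26 ± 0.059) fell, and the list was called at adjusted p = 0.00901 against Col-0_2 alone, 0.0455 against the mean of both sets and 0.0183 after quantile normalisation. Iron deficiency genes counted 6 up and 2 down of 8 (camera adjusted p = 0.102, called at 0.0255 against Col-0_2 alone and 0.0455 against the mean of both sets). BHLH100 rose by 5.04 ± 0.11 and BHLH038 by 5.24 ± 0.15, while the ferritin gene FER1 (AT5G01600) fell from 4382 ± 88.3 and 7879 ± 136 to 475 ± 56.5. FER1 need not move with genes induced in iron-starved plants. The counts and this test of 1 shared direction therefore do not show a mixed response. Root genes counted 5 up and 5 down of 12 (camera adjusted p = 0.864). The root-hair genes PRP3 (-5.96 ± 0.11), COBL9 (AT5G49270) (-6.196 ± 0.23) and EXPA18 (AT1G62980) (-4.47 ± 0.19) fell. Phosphate starvation genes counted 5 up and 1 down of 9, auxin response genes 2 and 8 of 10, oxidative stress genes 9 and 3 of 13, heat shock genes 3 and 1 of 8, touch genes 3 and 1 of 6 and seed storage genes 2 and 0 of 9. Oxidative stress genes (camera adjusted p = 0.0529) were called at adjusted p = 0.0494 against Col-0_1 alone, 0.0254 against Col-0_2 alone, 0.0348 against the mean of both sets, 0.0421 after quantile normalisation and 0.047 without the filter. They were also called at 0.0453 without Col-0_1 replicate 3 and at 0.0487 and 0.0428 without Col-0_2 replicates 1 and 3. Auxin response was called at adjusted p = 0.0334 against Col-0_2 alone, and touch at 0.00245 against Col-0_1 alone and 0.0208 against the mean of both sets. Adjusted over the list alone, heat shock genes counted 1 up and 1 down, and the counts of the other lists did not differ. Among the largest changes over all genes, AT4G36700 rose by 9.58 ± 0.18, AT5G48430 rose by 8.66 ± 0.11 and the sucrose synthase gene SUS4 (AT3G43190) had a log2 fold change of -10.41 ± 0.37. AT5G54370 was listed at 0 in obe1-2 against 1668 ± 65.8 and 1168 ± 66.6, and AGP30 (AT2G33790), a root arabinogalactan protein gene, was listed at 0 against 1684 ± 85.7 and 744 ± 17.1.

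In obe1-2 15480 of 25085 genes changed, 7327 up and 8153 down, of which 8212 changed at least 2-fold, 3195 up and 5017 down. Of 13 called lists, 10 held with an estimated correlation, at camera adjusted p up to 0.0231 for senescence and at 0.02 for photosynthesis. Against Col-0_2 alone 17136 genes differed, 8068 higher and 9068 lower, and camera called 17 lists.

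**Figure D2:**
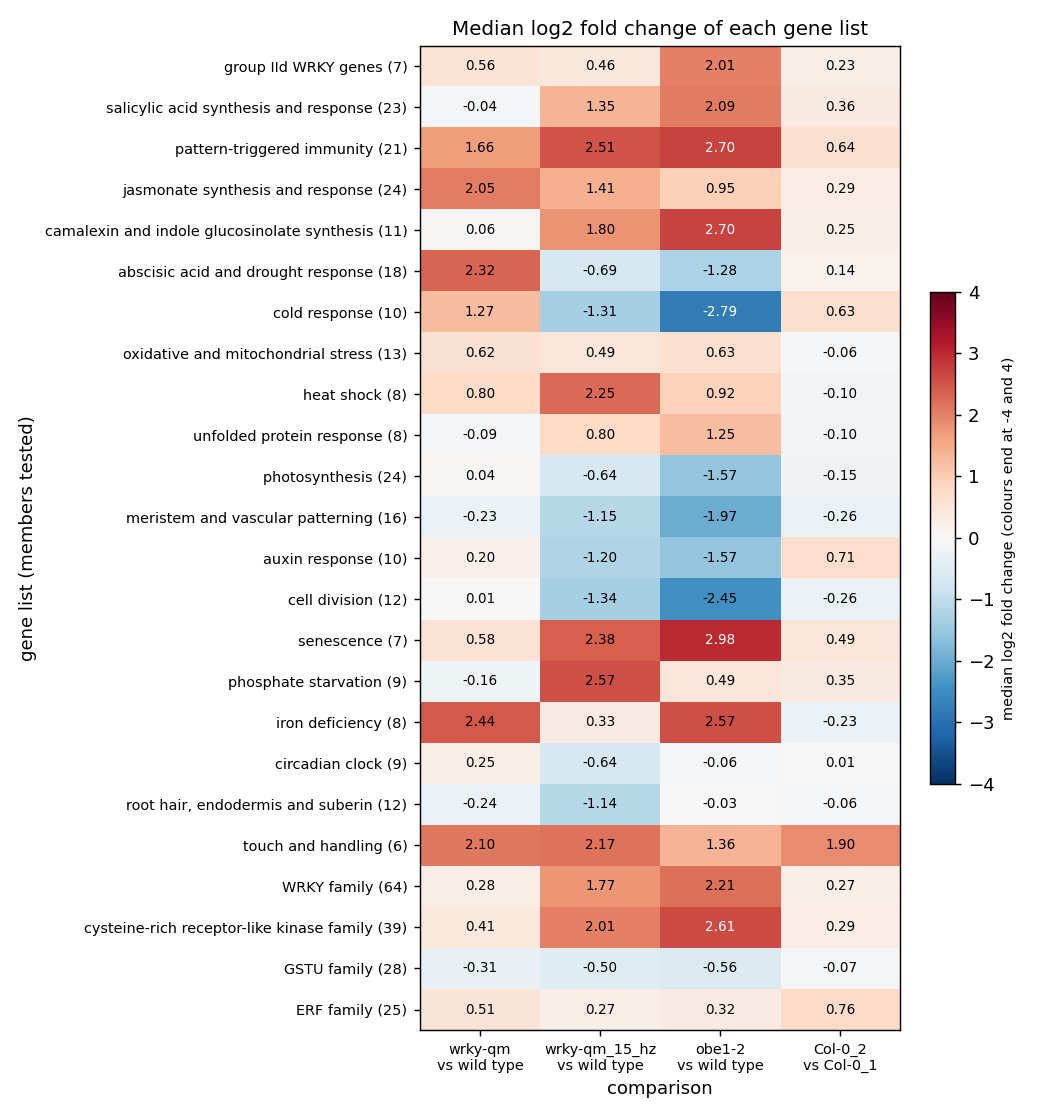
Median log2 fold change of each gene list against the mean of both wild-type sets for the 3 mutants, and of Col-0_2 against Col-0_1. Rows are lists with the number of members tested, colours end at -4 and 4, and the seed storage list is left out because 4 of its 9 members were listed at 0 in each wild-type set. Pattern-triggered immunity stood at 1.66, 2.51 and 2.702, and cell division at 0.01, -1.34 and -2.45, in wrky-qm, wrky-qm_15_hz and obe1-2.

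The wild-type sets, of the same genotype, differed in touch and immune genes. All 6 touch genes were higher in Col-0_2 (median log2 difference 1.897, camera adjusted p = 1e-13), with TCH3 at 1061 ± 61.3 against 281 ± 33.2 and TCH4 at 1586 ± 138 against 519 ± 58.97. Pattern-triggered immunity genes were higher in 17 of 21 cases (median 0.64, camera adjusted p = 8.21e-14) and ERF family genes in 13 of 25 (median 0.76, camera adjusted p = 1.12e-08). Photosynthesis genes were lower in 10 of 24 cases and higher in 1 (median -0.16, camera adjusted p = 1.22e-05), a call lost at adjusted p = 0.0834 with an estimated correlation. The genes of largest difference included BGLU19 (AT3G21370), at 102 ± 7.52 in Col-0_2 and 2.47 ± 1.45 in Col-0_1, and AT3G01345, at 436 ± 29.1 in Col-0_1 and 5.84 ± 4.51 in Col-0_2. AT2G10965 stood at 98.7 ± 16.95 in Col-0_1 and was listed at 0 in each of the other 4 groups. In total 5824 of 25085 genes differed by limma, 3436 higher and 2388 lower in Col-0_2, and 767 differed at least 2-fold. Camera called 16 of 25 lists between the sets, of which 10 held with an estimated correlation. The called lists included salicylic acid (median 0.362, camera adjusted p = 0.000123) and phosphate starvation (median 0.354, camera adjusted p = 0.00173). They also included CRK (median 0.294, camera adjusted p = 0.0142) and abscisic acid and drought (median 0.139, camera adjusted p = 0.0269). The abscisic acid call was lost at adjusted p = 0.0952 with an estimated correlation. This difference between sets is carried by any comparison that crosses them.

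Adding the WRKY15 mutation to the genotype is what the labels give as the difference between wrky-qm_15_hz and wrky-qm, which were compared directly. Abscisic acid and drought genes were lower in wrky-qm_15_hz in 16 of 18 cases and higher in 1 (median log2 difference -3.05, camera adjusted p = 4.46e-11). HAI2 (AT1G07430), a phosphatase gene induced by abscisic acid, stood at 9.53 ± 9.599 against 4889 ± 271, and HSFA6A (AT5G43840) at 1.53 ± 1.29 against 1119 ± 85.7. All 8 members of the iron deficiency list were lower (median -2.09, camera adjusted p = 5.79e-05), as were all 12 cell division genes (median -1.29, camera adjusted p = 0.000147). The 8 include FER1, which need not move with genes induced in iron-starved plants, so the count does not show 1 shared iron response. Jasmonate genes were lower in 16 of 24 cases and higher in 7 (median -0.95, camera adjusted p = 0.0113). All 9 phosphate starvation genes were higher (median 2.87, camera adjusted p = 1.95e-07), as were 18 of 23 salicylic acid genes (median 1.39, camera adjusted p = 1.55e-06) and 29 of 39 CRK genes (median 1.59, camera adjusted p = 1.95e-07). PR1 showed the largest difference, at 4210 ± 298 against 1.92 ± 3.31, followed by the albumin gene SESA4 (AT4G27170), at 1408 ± 77.2 and listed at 0 in wrky-qm. Camera called 20 of 25 lists, of which 12 held with an estimated correlation. By limma 16154 genes differed, 7404 higher and 8750 lower in wrky-qm_15_hz, and 6733 at least 2-fold. After subtracting Col-0_2 from wrky-qm_15_hz and Col-0_1 from wrky-qm, 12597 genes differed.

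Between obe1-2 and wrky-qm, the abscisic acid and drought list was again lower, in 16 of 18 members (median -2.71, camera adjusted p = 3.86e-09), and cold response genes were lower in 8 of 10 (median -4.81, camera adjusted p = 0.000565). Photosynthesis genes were lower in obe1-2 in 22 of 24 cases (median -1.64, camera adjusted p = 3.83e-09) and cell division genes in 12 of 12 (median -2.504, camera adjusted p = 2.76e-05). Salicylic acid genes were higher in 21 of 23 cases (median 1.89, camera adjusted p = 5.03e-08) and group IId WRKY genes in 6 of 7 (median 1.41, camera adjusted p = 0.000759). The iron deficiency list did not differ by this test, with 3 members higher and 3 lower of 8 (median 0.13, camera adjusted p = 0.983). PR1 again showed the largest difference upward, at 28899 ± 842 against 1.92 ± 3.31 (limma adjusted p = 8.36e-17), and HAI2 was lower, at 1.42 ± 1.21 against 4889 ± 271. Camera called 17 of 25 lists, of which 14 held with an estimated correlation. By limma 17557 genes differed, 7799 higher and 9758 lower in obe1-2. Of these, 8752 differed at least 2-fold, 2992 higher and 5760 lower. Without a fold minimum, quantile normalisation gave 9390 higher and 8441 lower. With Col-0_2 subtracted from obe1-2 and Col-0_1 from wrky-qm, 14922 genes differed.

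A comparison of obe1-2 with wrky-qm_15_hz was added after the data were seen. All 24 photosynthesis genes were lower in obe1-2 (median log2 difference -0.91, camera adjusted p = 2.61e-15) and 11 of 12 cell division genes were lower (median -1.098, camera adjusted p = 3.73e-05). Phosphate starvation genes were lower in 8 of 9 cases (median -1.65, camera adjusted p = 2.36e-06), seed storage genes in 8 of 9 (camera adjusted p = 5.73e-07) and cold response genes in 8 of 10 (median -1.34, camera adjusted p = 0.000168). Iron deficiency genes were higher in 6 of 8 cases (median 2.74, camera adjusted p = 0.000145). Pattern-triggered immunity genes counted 11 higher and 6 lower of 21, and jasmonate genes 6 and 8 of 24, without a call (camera adjusted p = 0.0848 and 0.753). Other defence lists were called higher in obe1-2. Salicylic acid genes were higher in 13 of 23 cases with 0 lower (median 0.42, camera adjusted p = 2.16e-05). Camalexin and indole glucosinolate genes were higher in 7 of 11 with 0 lower (median 0.38, camera adjusted p = 0.000145). CRK genes were higher in 19 of 39 and lower in 3 (median 0.59, camera adjusted p = 3.97e-05). Camera called 17 of 25 lists, of which 13 held with an estimated correlation. By limma 11630 genes differed, 5086 higher and 6544 lower in obe1-2. Of these, 3354 differed at least 2-fold, 577 higher and 2777 lower. Without a fold minimum, quantile normalisation gave 5981 higher and 5611 lower.

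**Figure D3:**
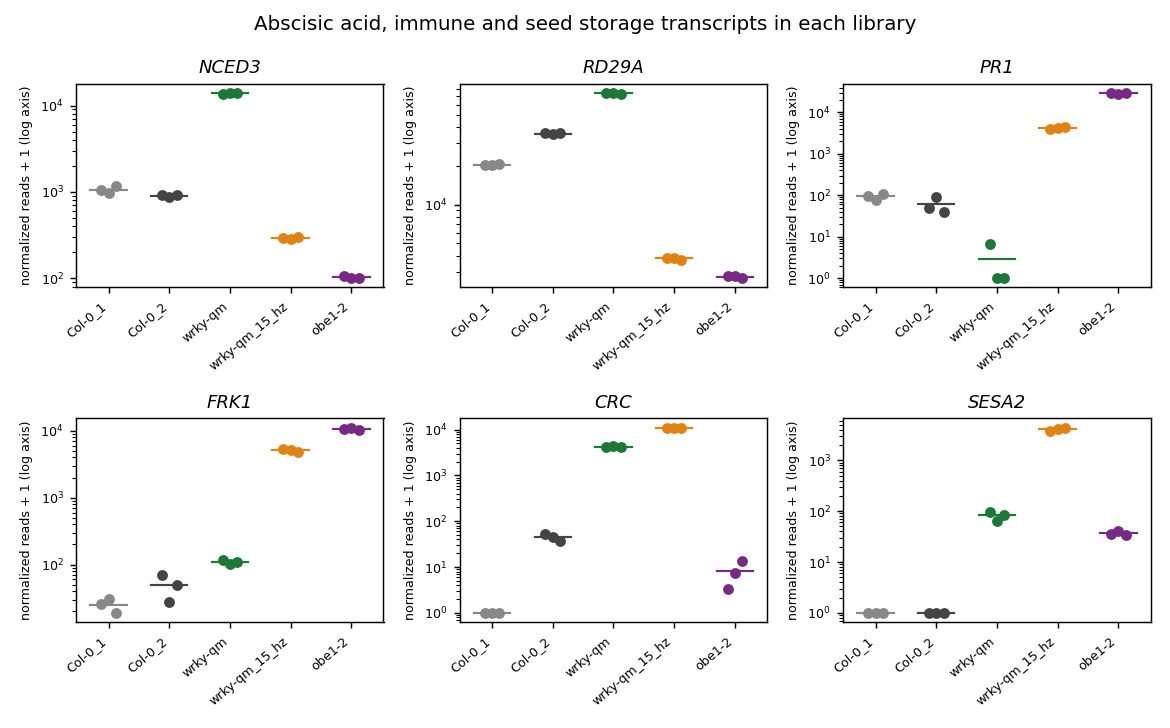
Normalised reads + 1 on a log axis for NCED3, RD29A, PR1, FRK1, CRC and SESA2. Each point is 1 library, each line a group mean, and the horizontal axis gives the 5 groups. NCED3 lay at 13790 in wrky-qm and at 293 and 101 in wrky-qm_15_hz and obe1-2, and PR1 at 1.92, 4210 and 28899 in the same order.

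Genes changed in the same direction were counted for each pair of mutants, because the series title places WRKY and PHD proteins in 1 complex. In all 3 mutants 1906 genes rose and 1119 fell. Those of largest change in every mutant included PAP85 (AT3G22640), a vicilin-like seed protein gene, at 59.98 ± 4.63, 564 ± 88.8 and 60.6 ± 10.5 in wrky-qm, wrky-qm_15_hz and obe1-2 and under 1 in both wild-type sets, and M17 (AT2G41260), a late embryogenesis gene (log2 fold changes 5.85 ± 0.34, 5.31 ± 0.34 and 5.36 ± 0.34). MRN1 fell in each mutant (-6.32 ± 0.51, -6.01 ± 0.51 and -7.12 ± 0.51), as did AGL44 (AT2G14210), a MADS-box gene of root nitrate responses (-4.12 ± 0.38, -4.39 ± 0.38 and -7.04 ± 0.38). Between wrky-qm and obe1-2, 2142 genes rose in both and 1442 fell in both, against 1135 and 929 for independent lists, and 1609 moved in opposite directions. Between wrky-qm_15_hz and obe1-2, 5677 rose in both and 5992 fell in both, against 1944 and 2238 for independent lists, and 203 moved in opposite directions. Between wrky-qm and wrky-qm_15_hz, 2186 rose in both and 1247 fell in both, against 1031 and 784, and 1403 moved in opposite directions. The numbers for independent lists treat every gene tested as equally likely to be called. Genes of few reads are called less often in any mutant, which by itself raises overlaps above these numbers and was not corrected for. In 20 simulations of unchanged groups against the same wild-type libraries at most 1 gene was called per group, so their overlap of 0 sets no level for lists of this size. With the first mutant of a pair against Col-0_1 and the other against Col-0_2, same-direction counts were 5724, 13145 and 5535 in that order. The other way round they were 4610, 12826 and 4402. In the first way 3156 rose and 2568 fell in both wrky-qm and obe1-2, against 1771 and 1670 for independent lists. In the second way these were 2611 and 1999, against 1889 and 1830. For wrky-qm and wrky-qm_15_hz they were 3203 and 2332 against 1647 and 1444 in the first way. In the second way they were 2635 and 1767 against 1797 and 1649. In the first way the opposite counts were 2454, 766 and 2157. Of the 2454, 1304 rose in wrky-qm and fell in obe1-2, against 1991 for independent lists, and 1150 fell and rose, against 1486. Of the 2157, 1027 rose in wrky-qm and fell in wrky-qm_15_hz, against 1722, and 1130 fell and rose, against 1381. In the second way the opposite counts were 4055, 629 and 3863. Of the 4055, 2040 rose in wrky-qm and fell in obe1-2, against 2139 for independent lists, and 2015 fell in wrky-qm and rose in obe1-2, against 1616. Of the 3863, 1849 rose in wrky-qm and fell in wrky-qm_15_hz, against 1927, and 2014 fell in wrky-qm and rose in wrky-qm_15_hz, against 1537.

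Across genes, which are not independent replicates, the log2 fold changes of wrky-qm and obe1-2 had a Pearson r of 0.25 as the mean of the 2 ways of splitting the wild-type sets, 0.322 and 0.178. With shared wild-type sets r was 0.31 and the covariance 0.474, against 0.331 and 0.028 in simulated unchanged groups, so shared controls alone gave an r of this size but not a covariance of this size. The split value in simulated groups was -0.322. The simulated mutants were placed midway between the wild-type sets, which by itself makes a split value negative. It therefore sets no level for the split values of the real mutants. For wrky-qm_15_hz and obe1-2 the split value was 0.795 and the shared value 0.845, with a covariance of 2.08, and for wrky-qm and wrky-qm_15_hz 0.307 and 0.383, with a covariance of 0.457. Against Col-0_2 alone, r of wrky-qm_15_hz and obe1-2 was 0.838.

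**Figure D4:**
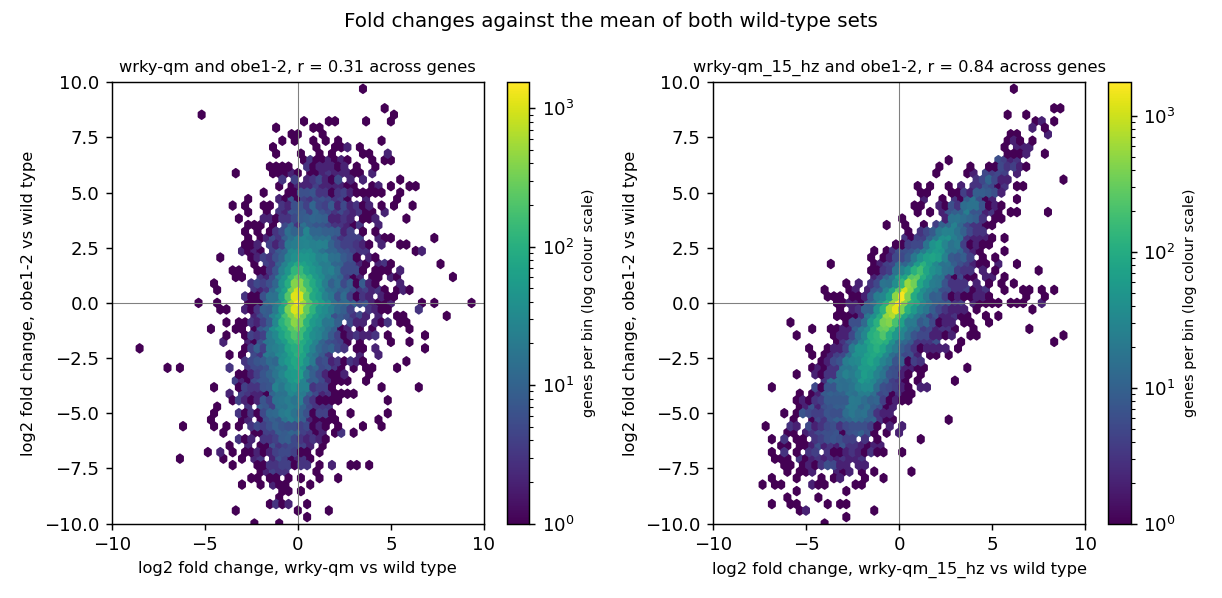
Log2 fold change in obe1-2 (vertical axis) against that in wrky-qm (left) and in wrky-qm_15_hz (right), each against the mean of both wild-type sets. Hexagons are coloured by the number of genes on a log scale, and both axes end at -10 and 10. The correlation across genes was 0.31 on the left and 0.845 on the right.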

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

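The difference tests against wrky-qm were planned before the data were seen. The test between obe1-2 and wrky-qm_15_hz was chosen after the data were seen, and the tests of explanations in this part were chosen after these results were seen. Genes changed at least 2-fold in opposite directions counted 218 between wrky-qm and wrky-qm_15_hz (133 up and 85 down in wrky-qm), 281 between wrky-qm and obe1-2 (214 up and 67 down in wrky-qm) and 34 between wrky-qm_15_hz and obe1-2 (31 up and 3 down in wrky-qm_15_hz). These were flagged because each gene passed in both mutants with the opposite sign. The abscisic acid and drought list differed by a median of -3.05 on the log2 scale between wrky-qm_15_hz and wrky-qm (camera adjusted p = 4.46e-11) and by -2.71 between obe1-2 and wrky-qm (camera adjusted p = 3.86e-09). The cold response list differed by -4.81 between obe1-2 and wrky-qm (camera adjusted p = 0.000565). These were flagged as differences between mutants by a direct test.

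The difference in the abscisic acid list between wrky-qm and the other mutants was weighed first. The falls in those mutants were not called by the main rule, but were called against Col-0_2 alone and against the mean of both sets. A difference between growth sets of the size seen between the wild-type sets does not account for it, since the upper quartile of the list's differences was 0.751 between wild types and the lower quartile 1.96 between mutants. Handling at harvest cannot be told apart, because the touch list moved both ways, with a median of 0.145 between wrky-qm_15_hz and wrky-qm (3 higher, 2 lower) and -0.65 between obe1-2 and wrky-qm (2 higher, 3 lower). Another hour of harvest cannot be told apart from an effect of genotype either. CCA1 and PRR9 differed between the other mutants and wrky-qm by a median of -3.43 on the log2 scale, over both genes and both comparisons. The whole clock list holds genes that peak at different hours. Its median difference from wrky-qm was -0.79 in wrky-qm_15_hz (2 higher, 6 lower of 9) and -0.651 in obe1-2 (3 higher, 6 lower). As a biological explanation, the mutations named in the labels could alter abscisic acid signalling differently, which these data do not test.

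Seed storage transcripts in wrky-qm and wrky-qm_15_hz were weighed second. Seed material of the same kind in both mutants would give the same SESA2 to CRC ratio if both transcripts were lost equally fast. The log2 ratios were -5.70 ± 0.331 in wrky-qm and -1.41 ± 0.0906 in wrky-qm_15_hz (mean ± SD, n = 3), a difference of 4.29. Neither the rate of loss nor reads shared between SESA2 and its close copies were tested, so the ratio does not exclude the same material. Dry seeds carried into wrky-qm_15_hz would raise the late embryogenesis genes EM1 and GEA6 too, and these were lower there than in wrky-qm by a mean log2 difference of -2.66. Both lay near the floor in wrky-qm_15_hz, at 24.0 normalised reads or fewer, and M17, another late embryogenesis gene, rose in all mutants (5.85, 5.31 and, without a seed storage call, 5.36 in obe1-2) and decides nothing, so dry seeds cannot be told apart from the other explanations. Carry-over of developing seeds, and seed genes switched on in seedlings, could each give such levels and were not tested.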

How the results depend on the processing

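Settings were planned before the data were seen, except a minimum mean of 50 and all settings of the comparison of obe1-2 with wrky-qm_15_hz, which were added afterwards. The DESeq2 test, DESeq2 size factors and the filter by counts were not run because the table holds no counts, and quantile normalisation and a limit on values took their place. No named gene turned its direction under any setting, and no called list did after quantile normalisation. Of lists without a call, the medians of camalexin (0.056 to -0.02) and cell division (0.012 to -0.076) in wrky-qm and of root genes in obe1-2 (-0.029 to 0.129) changed sign after quantile normalisation. Of 413 results on single genes and lists, 403 or more kept their side of the threshold under each setting that tested all of them, apart from the 2-fold minimum, under which 48 were no longer called. Quantile normalisation ended 2 calls and added 7, a pseudocount of 0.1 ended 3, the estimated correlation ended 5, and Col-0_1 alone, Col-0_2 alone and the mean of both sets added 7, 9 and 10. Genes of few reads limit what can be called, and the filter left 26381 genes without a minimum and 19724 with a mean of 50.

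With a 2-fold minimum, which by construction counts fewer genes, 2262 genes changed in wrky-qm, 6342 in wrky-qm_15_hz and 8212 in obe1-2. The direct comparisons then gave 6733 between wrky-qm_15_hz and wrky-qm, 8752 between obe1-2 and wrky-qm, 767 between the wild-type sets and 3354 between obe1-2 and wrky-qm_15_hz. Genes changed the same way were 1182 in wrky-qm and obe1-2, 5408 in wrky-qm_15_hz and obe1-2 and 1173 in wrky-qm and wrky-qm_15_hz. With 1 wild-type set in place of both, fewer conditions had to be met. Against Col-0_1 alone 10126 genes changed in wrky-qm, 6201 the same way in wrky-qm and obe1-2 and 6071 in wrky-qm and wrky-qm_15_hz, and against Col-0_2 alone 10549 changed in wrky-qm. Against the mean of both sets the counts were 11058, 5857 and 5668. With Col-0_1 for the first mutant and Col-0_2 for the other, 5724 changed the same way in wrky-qm and obe1-2 and 5535 in wrky-qm and wrky-qm_15_hz.

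The fold change correlation of wrky-qm and obe1-2, 0.25 as planned, was 0.392 against Col-0_1 alone, 0.279 against Col-0_2 alone, 0.31 against the mean of both, 0.322 and 0.178 in the 2 split orders, 0.267 after quantile normalisation, 0.214 with a pseudocount of 0.1 and 0.269 at a mean of 50. The cause was not tested. Leaving out each library in turn gave 0.243 to 0.25 for this correlation, 6002 to 6279, 12744 to 13092, 14827 to 15127 genes changed in wrky-qm, wrky-qm_15_hz and obe1-2, and 8 to 9, 16 to 17, 13 to 14 lists called.

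Replicate numbers are shared between groups but mark no pairing in the labels. Libraries of the same number correlated between -0.098 and 0.05 over 30 pairs, with 0 over 0.1, and 0 libraries correlated best with their own number in every group. With the replicate number as a block, 6636, 13468 and 15444 genes changed in wrky-qm, wrky-qm_15_hz and obe1-2, the direct comparisons gave 16066, 17506, 5686 and 11480, and 3515, 11619 and 3378 genes changed the same way. The correlation was 0.25 and 8, 16 and 13 lists were called under this block. One call of a named gene was lost under the block, HSP17.6A in obe1-2, at limma adjusted p = 0.0609.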

Other observations

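What the random splits would show was written before they were run, though after the real counts were seen, and the comparison of obe1-2 with wrky-qm_15_hz was added after the data were seen. The tests of why wrky-qm_15_hz resembled obe1-2 were chosen after that was seen. The circadian clock list was chosen to mark the hour of harvest. Of its 9 genes, 3 rose and 1 fell in wrky-qm, 2 rose and 5 fell in wrky-qm_15_hz and 4 rose and 4 fell in obe1-2. Camera made no call except in wrky-qm against the mean of both sets (adjusted p = 0.02). The list pools genes that peak at different hours, so these counts and a test of 1 shared direction cannot show whether the hour differed. Directly, the list was lower in wrky-qm_15_hz than in wrky-qm (camera adjusted p = 0.0172), lost at adjusted p = 0.115 with an estimated correlation. It was higher in obe1-2 than in wrky-qm_15_hz (camera adjusted p = 0.0111), lost at adjusted p = 0.101 with an estimated correlation. Between obe1-2 and wrky-qm the list was not called, with 3 members higher and 6 lower in obe1-2 (camera adjusted p = 0.39). Adjusted over the list alone, 4 rose in wrky-qm and the other counts did not differ. The pseudo-response regulator gene PRR9 (AT2G46790) had log2 fold changes of 1.502 ± 0.17, -3.57 ± 0.17 and -2.49 ± 0.17 in wrky-qm, wrky-qm_15_hz and obe1-2. CCA1 (AT2G46830), a morning-phased clock gene, had a log2 fold change of -1.85 ± 0.097 in wrky-qm_15_hz and -2.100 ± 0.097 in obe1-2 (limma adjusted p = 1.29e-06 and 1.86e-08) and did not pass in wrky-qm.

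Among tau-class glutathione transferase genes, 3 rose and 10 fell of 28 in wrky-qm (11 fell adjusted over the list alone), 10 rose and 15 fell in wrky-qm_15_hz and 10 rose and 14 fell in obe1-2, with no camera call except in wrky-qm against Col-0_1 alone (adjusted p = 0.0471). GSTU20 (AT1G78370) had log2 fold changes of -1.79 ± 0.035 in wrky-qm_15_hz and -2.45 ± 0.035 in obe1-2, and GSTU27 (AT3G43800) rose there by 1.51 ± 0.043 and 1.77 ± 0.043. Ethylene response factor genes counted 9 up and 4 down of 25 in wrky-qm (10 up adjusted over the list alone), 11 up and 4 down in wrky-qm_15_hz and 10 up and 7 down in obe1-2, with no camera call against both sets. That list was called against Col-0_1 alone at adjusted p = 3.37e-05 in wrky-qm and 0.00463 in wrky-qm_15_hz, and at 0.0365 in wrky-qm_15_hz against the mean of both sets. ERF11 (AT1G28370), a repressor-type factor, rose by 4.56 ± 0.19, 3.24 ± 0.19 and 2.499 ± 0.19 in the 3 mutants. ERF8 (AT1G53170) rose by 3.61 ± 0.11 in wrky-qm and fell in wrky-qm_15_hz (log2 fold change -0.93 ± 0.11) and obe1-2 (-2.78 ± 0.11). OBE1 and OBE2 both rose in wrky-qm and wrky-qm_15_hz and both fell in obe1-2. The rise of OBE1 in wrky-qm_15_hz (limma adjusted p = 0.00735) was lost after quantile normalisation at limma adjusted p = 0.0551.

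For changed genes, 1 of 100 splits, the real one, gave a count as large. The real and highest other counts were 6743 and 6400 in wrky-qm, 13541 and 13388 in wrky-qm_15_hz and 15480 and 15369 in obe1-2. The deposited values had the form of an adjustment within each real group, which may favour the real grouping. Replicates may also be technical, so these splits do not exclude chance differences between cultures. The highest other counts came from splits that kept the 3 mutant libraries together and mixed only wild types, and so kept the real contrast. Splits that divided the mutant gave at most 1, 1005 and 88 genes. For the number of lists called, 11, 12 and 11 of 100 splits gave as many as the real 8, 16 and 13, with highest others of 13, 17 and 15, so chance cannot be excluded by this count. In each mutant 9 of those splits kept 2 mutant libraries in 1 group and so carried part of the real contrast, and splits with 1 mutant library in the group gave at most 4, 3 and 3 lists. For genes changed the same way, 1 of 100 splits gave as many as the real 3584, 11669 and 3433, with a highest other of 0 each. Splits that divide the mutants call few genes, so an overlap of 0 follows, and these splits do not test whether an overlap exceeds chance for lists of this size. For the direct comparisons, 1 of 10 splits gave as many genes, with real values of 16154, 17557, 11630 and 5824 and highest others of 0, 0, 1 and 2, and 10 splits are too few.

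The wrky-qm_15_hz libraries resembled obe1-2 more than wrky-qm, with group profiles correlated at 0.949 between wrky-qm_15_hz and obe1-2, at 0.849 between wrky-qm_15_hz and wrky-qm and at 0.983 between the wild-type sets. Material of obe1-2 mixed into seedlings like wrky-qm does not account for the whole, since OBE1, at 3574 normalised reads or more, allowed a share of at most 0.262, and the 6671 genes with a mean of at least 50 in a mutant and at least 2-fold different between obe1-2 and wrky-qm needed shares with a lower quartile of 0.565. A partial share cannot be told apart, because OBE1 lay below the lowest wrky-qm value of 4401 but OBE2, at 6586 or more, above the highest of 5575. The choice of wild-type libraries does not account for the resemblance. The lowest correlation of fold changes with obe1-2 was 0.779 over 6 choices and the highest with wrky-qm was 0.476. A smaller share of green tissue would raise root genes or leave them unchanged. In wrky-qm_15_hz the medians were -1.14 for root genes and -1.34 for cell division, which argues against it as the whole cause there. In obe1-2 cell division fell (median -2.45), while root genes moved both ways, 5 up and 5 down of 12 (median -0.029), and so decide nothing. Dividing cells can lie in green tissue, so a smaller green share cannot be told apart in obe1-2. Growth of these 2 mutants side by side, away from both wild types, was not tested and could add to the resemblance. So could the mutation of 1 WRKY15 copy that the labels name, a biological explanation that these data do not test.

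Zeros were stored as a tiny value in Col-0_1 (8177 genes) and wrky-qm (7949) and as exact 0 in Col-0_2 (8037), obe1-2 (9106) and wrky-qm_15_hz (8431).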
